A study of Homo sapiens with 6 samples.

How the data were processed

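Total RNA from KGN cells, a human granulosa-like line derived from an ovarian granulosa cell tumour, was extracted with TRIzol and checked on an Agilent Bioanalyzer, and libraries were prepared for an Illumina HiSeq instrument, per the labels' protocols. The labels give 6 libraries in 2 groups of 3, OE-NC (genotype given as wild type) and OE-SOX3 (genotype given as SOX3 overexpression). They do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

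The authors deposited a table of 16626 gene symbols with 1 expression value per library. Its header does not name the unit. The values were taken as FPKM, reads scaled to the length of the gene and to the library total, because the deposited FPKM values are whole multiples of a step that depends on the gene's length. HISAT2, HTSeq and RSEM and the hg38 build are named without versions or roles, per the submitters' processing notes. Which of these tools made the values, the gene annotation, the read layout and any strand setting are not given in the sources used here. A value per kilobase divides by a fixed gene length, so a change in transcript length or a length-dependent loss of RNA in a library enters the values as a change in expression.

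The length steps were solved for whole reads. A set of whole reads and a gene length in whole base pairs fitted all 6 values of 16278 of the 16278 genes above 0 (100%, within 0.02 reads). The other 348 genes were at 0 in every library. The library totals that fitted were 18039929 to 20335307 reads. The solution with the fewest reads was taken, so reads that share a common divisor in all 6 libraries are understated. On simulated reads for 15960 genes the recovered reads were exact for 96% of genes. Recovered reads were used for depth, for a comparison of library pairs and for 1 alternative test. The pairs were compared by chi-square over tested genes with more than 20 reads in the pair. Recovered reads also gave counting intervals of the ratio between groups (95%, exact binomial, covering counting error only). The table holds no counts, so no count test was the main result.

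Values were tested on the log2 scale after adding a pseudocount of 1 FPKM. A log2 fold change is therefore on the log2(FPKM + 1) scale and understates the change of low genes. Genes with a mean of at least 1 FPKM in either group were kept (11131 genes). OE-SOX3 was compared with OE-NC in a limma-trend fit to all 6 libraries without covariates (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. In this text, rose and fell refer to genes past that threshold. The scripts also used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3. On simulated reads for OE-SOX3 against OE-NC (10651 genes tested, 200 of them changed), the fit recovered 76.9% of genes changed 1.5-fold, 96.9% of those changed 2-fold and 100% of those changed 4-fold, and 4.7% of its calls were false. The simulated genes were independent and shared the same dispersion, with no gene length trend and no library apart from its group. These shares therefore need not hold for the real comparison.

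A set of 32 gene lists (pathways, cell states and markers of other cell types) was fixed before the data were examined, as were the test, the threshold and the rule for named genes. The 30 lists with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also takes the residual degrees of freedom of the fit, which are few with 6 libraries. A call lost there need not reflect correlation between genes. The p53 list, for example, had an estimated correlation of 0.004, below the preset, and its unadjusted camera p went from 0.00217 to 0.0299. Fry tests each list on its own, against the case that no member changed, so it does not compare a list with the other genes. In simulated data for the same comparison, camera called a list of 40 genes shifted by 0.5 (log2) and 0 of 100 unshifted lists. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.751. This run therefore does not show how camera behaves on correlated genes. The rule named SOX3 and SPP1, the 10 largest rises and the 10 largest falls among called genes with a symbol, at least 1 FPKM in a group and groups that did not overlap, and up to 4 called members of each list with the smallest adjusted p. Genes named outside the rule are marked as chosen after their values were seen, and some genes that the rule takes are not reported here.

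Coordinates come from GENCODE 29 (GRCh38), matched by symbol, and were not used to recount reads. Of 126 named genes with a position, 3 (CD68, PRC1 and ACAT2) had more than 50% of their exon bases inside exons of another gene, so their values are uncertain. Length and GC content were available for 98.1% of the tested genes.

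The labels give replicate numbers 1 to 3 in each group. Whether these numbers pair the libraries was checked before the fits were compared. Deviations from the group means correlated at 0.486, 0.243 and 0.25 across genes between same-numbered libraries (0.464, 0.236 and 0.276 after length and GC trends were removed), although OE-NC 3 correlated slightly more with OE-SOX3 2 (0.282). Deviations within a group sum to 0 for each gene, so a difference shared by the libraries numbered 1 can alone give positive values among numbers 2 and 3. Differently numbered libraries among these correlated similarly (0.282 and 0.227), so the values do not pair numbers 2 and 3. Any pairing rests on these correlations alone, and a fit with the replicate number as a block is reported where it changed a call. The other alternatives were the filter on low values, a pseudocount of 0.1, leaving out each library, a 2-fold minimum and, chosen after seeing the data, other scalings, removal of length and GC trends (splines with 4 degrees of freedom), limma-voom on recovered reads and limma's treat against 1.2-fold.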

Results

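RNA from 6 libraries of KGN cells was sequenced, 3 labelled OE-NC and 3 labelled OE-SOX3. KGN is a steroidogenic human granulosa-like line, and SOX3 is an X-linked transcription factor of the SOX family best known from the developing nervous system. The comparison asks which transcripts differ between cells overexpressing SOX3 and their control, and the series title directs attention to proliferation, apoptosis, PI3K/AKT signalling and the SPP1 gene. Expression was given as FPKM for 16626 genes, from 18039929 to 20335307 reads per library.

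SOX3 transcript was near 0 FPKM in OE-NC cells and present in every OE-SOX3 library. Its mean was 0.0808 ± 0.0582 FPKM (SD, n = 3) in OE-NC and 14.1 ± 0.374 FPKM (SD, n = 3) in OE-SOX3. The gene has 1 annotated coding exon (chromosome X, 140502985 to 140505116, minus strand, GRCh38). OE-NC libraries held 3, 6 and 1 reads of it and OE-SOX3 libraries 579, 547 and 540. Per unit depth the reads differed 172-fold (95% interval 93.1 to 359, counting error only). The log2 fold change was 3.81 (SE 0.06, limma adjusted p = 1.97e-07). This value depends on the processing. It was 6.35 with a pseudocount of 0.1 and 7.45 in limma-voom on recovered reads. With every library scaled to the same, larger sum of FPKM it was 5.17, and that scaling also raises every value against the pseudocount of 1.

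SPP1, which encodes the secreted phosphoprotein osteopontin, had the largest rise of any tested gene on the log2(FPKM + 1) scale. It went from 2.78 ± 0.399 FPKM (SD, n = 3) in OE-NC to 605 ± 20.1 FPKM (SD, n = 3) in OE-SOX3. The gene lies on chromosome 4 (87975650 to 87983426, plus strand, GRCh38), and no other annotated exon overlaps its exons. The reads rose from 284 in all OE-NC libraries together to 59913 in OE-SOX3, a ratio per unit depth of 217 (95% interval 193 to 245, counting error only). The log2 fold change was 7.33 (SE 0.09, limma adjusted p = 4.99e-08). Among the 10 tested genes for osteopontin, its receptors and its proteases, 8 rose, 0 fell and 2 did not pass. Besides SPP1 itself, they included PLAU, the urokinase plasminogen activator (14.2 to 23.7 FPKM), and the integrin subunits ITGAV (64.7 to 143 FPKM) and ITGA4 (8.96 to 18.7 FPKM). Adjusted over the list alone, 8 changed. The list's median log2 fold change was 0.65 and its mean 1.28 (camera adjusted p = 0.00216; adjusted p = 0.211 with an estimated correlation). SPP1 is part of this list and the list was not tested without it, so the result is not independent of the rise of SPP1.

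**Figure D1:**
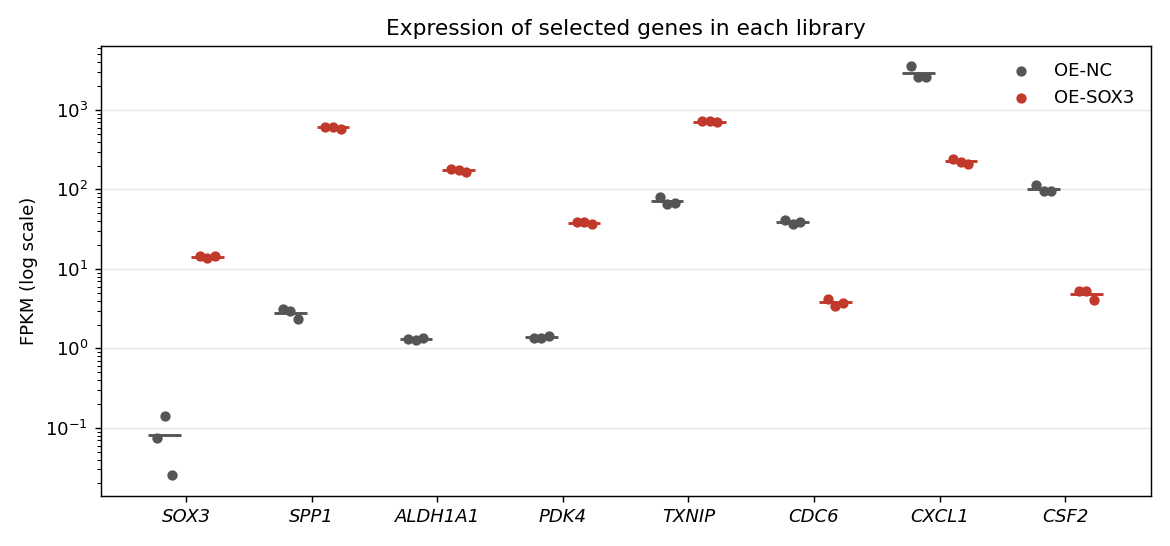
FPKM (vertical log axis) of 8 genes named by the fixed rule in each of the 6 libraries, with grey points for OE-NC, red points for OE-SOX3 and a bar at each group mean (n = 3). SPP1 lies near 2.78 FPKM in OE-NC and 605 FPKM in OE-SOX3, and CSF2 near 102 and 4.85 FPKM.

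Changes were widespread. ALDH1A1, a retinaldehyde dehydrogenase, rose from 1.32 ± 0.0401 to 175 ± 9.08 FPKM, and the serine protease inhibitor SERPINA3 rose from 1.35 ± 0.256 to 70.7 ± 4.35 FPKM (SD, n = 3 per group). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 1.38 to 37.8 FPKM, and TXNIP, a thioredoxin-binding protein that limits glucose uptake, rose from 71.2 to 713 FPKM. The clock repressor NR1D1 (1.1 to 21.8 FPKM), TCIM (0.0845 to 12.3 FPKM), the cell adhesion gene NRCAM (0.462 to 13.1 FPKM) and the matrix gene POSTN (1.16 to 19.4 FPKM) completed the largest rises. The largest fall on that scale was in CSF2, the cytokine GM-CSF, from 102 ± 10.3 to 4.85 ± 0.73 FPKM (SD, n = 3 per group). The chemokines CXCL1 (2919 to 225 FPKM) and CCL20 (43.9 to 3.9 FPKM) also fell, as did the fatty acid-binding protein gene FABP3 (69.9 to 3.47 FPKM) and the AP-1 subunit gene FOSL1 (84.3 to 9.58 FPKM). The replication genes CDC6 (39.1 to 3.8 FPKM) and FEN1 (130 to 15.9 FPKM) were among the 10 largest falls, together with TCF19 (76.0 to 9.07 FPKM), the neurofilament gene NEFM (7.94 to 0.231 FPKM) and ANKRD1 (91.3 to 11.7 FPKM).

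In all, 7686 of 11131 tested genes (69.1%) passed the threshold, 3665 higher and 4021 lower in OE-SOX3. Of these, 616 were at least 2-fold higher and 732 at least 2-fold lower on the log2(FPKM + 1) scale. The groups did not overlap for 8457 genes (76%, where chance gives 10%). The median log2 fold change of tested genes was -0.03. Scaling every library to the same, larger sum of FPKM moved this median to 0.10 and the share of higher genes among the changed from 47.7% to 57.5%, so small changes in either direction are relative to the scaling. OE-NC replicate 1 stood apart from the other OE-NC libraries. Across tested genes it correlated at 0.986 with each of them, against 0.998 between those, and the changed genes numbered 9076 without it. Its difference from them followed gene length (Spearman correlation across genes -0.508, where genes are not independent replicates). Length correlated at 0.239 with the log2 fold change between groups, and at 0.161 without that library. Recovered reads differed by a chi-square per degree of freedom of 1.76 between OE-NC 2 and 3 and 2.09 between OE-SOX3 2 and 3. Counting error alone gives about 1, and the other pairs within a group ranged from 4.64 to 61.49. Libraries 2 and 3 of each group thus differed little beyond counting error, and whether they are technical repeats is not given.

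**Figure D2:**
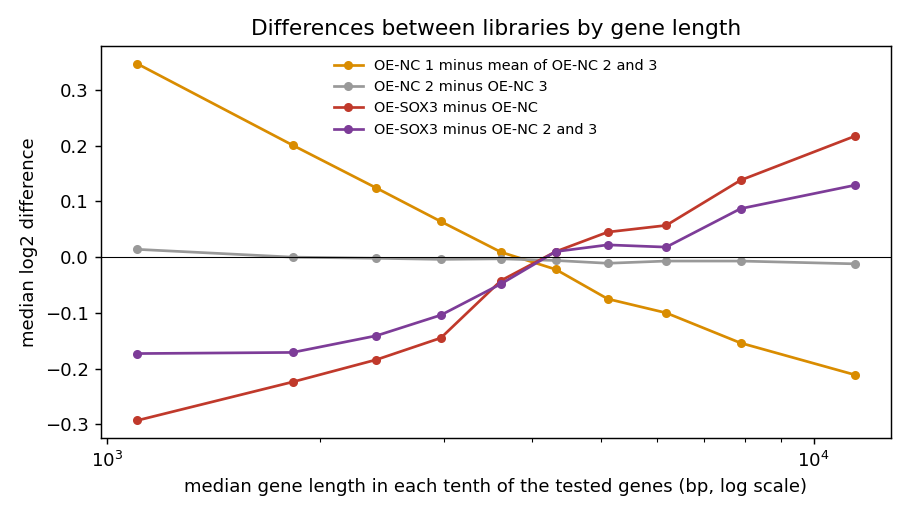
Median log2 difference (vertical axis) in 10 groups of tested genes ordered by gene length (horizontal log axis, bp), for OE-NC 1 against the other OE-NC libraries, OE-NC 2 against OE-NC 3, and OE-SOX3 against OE-NC with and without OE-NC 1. The shortest genes lie 0.35 higher in OE-NC 1 and the longest 0.21 lower (-0.21), while OE-NC 2 minus OE-NC 3 is 0.014 and -0.012 in these groups.

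Genes of DNA replication and the G1/S transition fell together. Of 40 tested, 38 fell, 1 rose and 1 did not pass, with a median log2 fold change of -1.92. The replicative helicase subunits MCM6 (57.5 ± 1.24 to 10.6 ± 0.345 FPKM), MCM3 (80.8 to 15.3 FPKM) and MCM5 (53.3 to 11.2 FPKM) fell, as did CDC25A, the phosphatase that activates cyclin-dependent kinases (5 to 0.558 FPKM; SD and n = 3 per group). The member that rose was CDK6, a G1 cyclin-dependent kinase (log2 fold change 0.49, named after its value was seen). Adjusted over the list alone, 39 changed. The camera adjusted p was 4.2e-14 (adjusted p = 0.211 with an estimated correlation).

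Mitotic genes also fell. Of 40 tested G2/M genes, 35 fell, 1 rose and 4 did not pass, and 36 changed when adjusted over the list alone. The spindle genes TPX2 (148 ± 11.1 to 54.4 ± 1.63 FPKM, SD, n = 3 per group) and PRC1 (127 to 57.9 FPKM), the centromere gene CENPI (10.2 to 3.19 FPKM) and the mitotic kinase gene PLK1 (69.9 to 36.3 FPKM) fell. MKI67, the Ki-67 proliferation marker, fell from 54.2 to 27.1 FPKM (chosen after its value was seen). The list median was -0.79 (camera adjusted p = 3.52e-08; adjusted p = 0.211 with an estimated correlation). Replication-dependent histone genes were higher where they were called. Of 9 tested, 6 rose and 0 fell, with a median of 0.67, and 8 changed when adjusted over the list alone, 7 higher and 1 lower (H4C8, 1.44 to 0.999 FPKM, named after its value was seen). The rises included H2AC6 (5.76 to 18.9 FPKM) and H2BC5 (2 to 5.67 FPKM), which belong to a family of near-identical copies, so their values are uncertain. The histone call (camera adjusted p = 0.0296; adjusted p = 0.221 with an estimated correlation) was lost with no filter on low values (median 0.12, adjusted p = 0.0999, range of adjusted p over alternatives 0.0156 to 0.0999).

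PI3K-AKT pathway genes changed in both directions. Of 44 tested core members, 21 rose, 10 fell and 13 did not pass (31 changed when adjusted over the list alone). The receptor and adaptor genes IGF1R (3.92 ± 0.407 to 9.55 ± 0.0771 FPKM, SD, n = 3 per group) and IRS2 (1.7 to 7.34 FPKM) rose, as did FOXO1 (1.85 to 5.9 FPKM) and FOXO4 (1.19 to 2.96 FPKM), transcription factors that AKT inhibits. Of the AKT kinases, AKT1 fell by 0.35 on the log2 scale and AKT2 stood at 11.6 and 11.8 FPKM without passing (both named after their values were seen). As a set the list did not pass (median 0.24, camera adjusted p = 0.051; adjusted p = 0.605 with an estimated correlation), although fry, which tests the list on its own, called it (fry adjusted p = 0.0023). With 69.1% of all tested genes changed, a fry call does not set a list apart from the other genes. In camera the list lay on the other side of the threshold in several alternatives (range 0.0329 to 0.411), among them without OE-NC replicate 2 (0.0329), without OE-NC replicate 3 (0.0365) and without OE-SOX3 replicate 1 (0.0445). Without OE-NC replicate 1 the median was 0.10 and the adjusted p 0.239.

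Apoptosis genes did not move one way. Of 31 pro-apoptotic genes tested, 11 rose, 12 fell and 8 did not pass (24 changed when adjusted over the list alone). TNFSF10, which encodes the death ligand TRAIL, rose from 0.731 ± 0.186 to 5.01 ± 0.302 FPKM (SD, n = 3 per group). The BH3-only gene BMF (0.17 to 1.8 FPKM) and the mitophagy receptor gene BNIP3L (18.9 to 37.5 FPKM) rose too, whereas CASP2, an initiator caspase, fell from 12.7 to 5.48 FPKM. The list median was -0.12 and its mean -0.02, while camera gave the opposite sign with an adjusted p of 0.993. Without OE-NC replicate 1 the median was -0.06. Of 21 anti-apoptotic genes, 7 rose, 10 fell and 4 did not pass (17 adjusted over the list alone; median -0.08, camera adjusted p = 0.864). BCL2 (1.63 to 0.388 FPKM), FAIM (4.63 to 1.51 FPKM) and BCL2L1, which encodes BCL-XL (91.8 to 56.9 FPKM), fell, and BIRC3, which encodes cIAP2, rose from 4.4 to 8.85 FPKM. BCL2L1 shares 43% of its exon bases with an antisense gene. Among 28 p53 target genes, 15 rose, 5 fell and 8 did not pass (20 adjusted over the list alone). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 76.7 to 184 FPKM, TP53INP1 from 1.94 to 8.83 FPKM, ZMAT3 from 2.7 to 9.97 FPKM and GDF15 from 2.83 to 10.2 FPKM. The p53 list had a median of 0.33 (camera adjusted p = 0.00722; adjusted p = 0.211 with an estimated correlation).

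Extracellular matrix genes rose together. Of 48 tested, 40 rose, 4 fell and 4 did not pass (45 adjusted over the list alone), with a median of 0.98. COL1A1, the alpha chain of type I collagen, rose from 320 ± 6.75 to 1835 ± 72.1 FPKM (SD, n = 3 per group), TGFBI from 153 to 862 FPKM and COL18A1 from 3.37 to 16.4 FPKM. The camera adjusted p was 4.54e-09 (adjusted p = 0.211 with an estimated correlation). Markers of theca and stromal cells, a list that shares genes such as COL1A1 and DCN with it, were higher in the same libraries (7 of 10, median 0.74, camera adjusted p = 0.0298; adjusted p = 0.211 with an estimated correlation). Of 14 integrin genes, 9 rose, 1 fell and 4 did not pass (10 adjusted over the list alone; median 0.53, camera adjusted p = 0.013; adjusted p = 0.388 with an estimated correlation). ITGA10 (0.726 to 4.9 FPKM) and ITGB4 (6.58 to 17.8 FPKM) rose, and ITGA7 fell (6.68 to 3.1 FPKM). TGF-beta and BMP target genes rose, with 20 of 24 tested higher, 1 lower and 3 not past the threshold (21 adjusted over the list alone; median 0.68). ID3, a BMP-responsive inhibitor of helix-loop-helix factors, rose from 15.7 to 79.9 FPKM, TGFB2 from 0.312 to 5.52 FPKM and PMEPA1 from 2.56 to 10.7 FPKM. That list's camera adjusted p was 1.4e-05 (adjusted p = 0.211 with an estimated correlation). Notch pathway genes rose as well, 7 of 10, with 1 lower and 2 not past (8 adjusted over the list alone). The target HES1 (0.358 to 5.69 FPKM), the receptor NOTCH3 (0.297 to 3.83 FPKM) and the ligand JAG1 (5.87 to 28.3 FPKM) were among them (median 0.90, camera adjusted p = 0.0154; adjusted p = 0.221 with an estimated correlation). The Notch median ranged from 0.18 to 1.56 over alternatives, with camera adjusted p from 0.00791 to 0.0404 at the preset correlation.

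**Figure D3:**
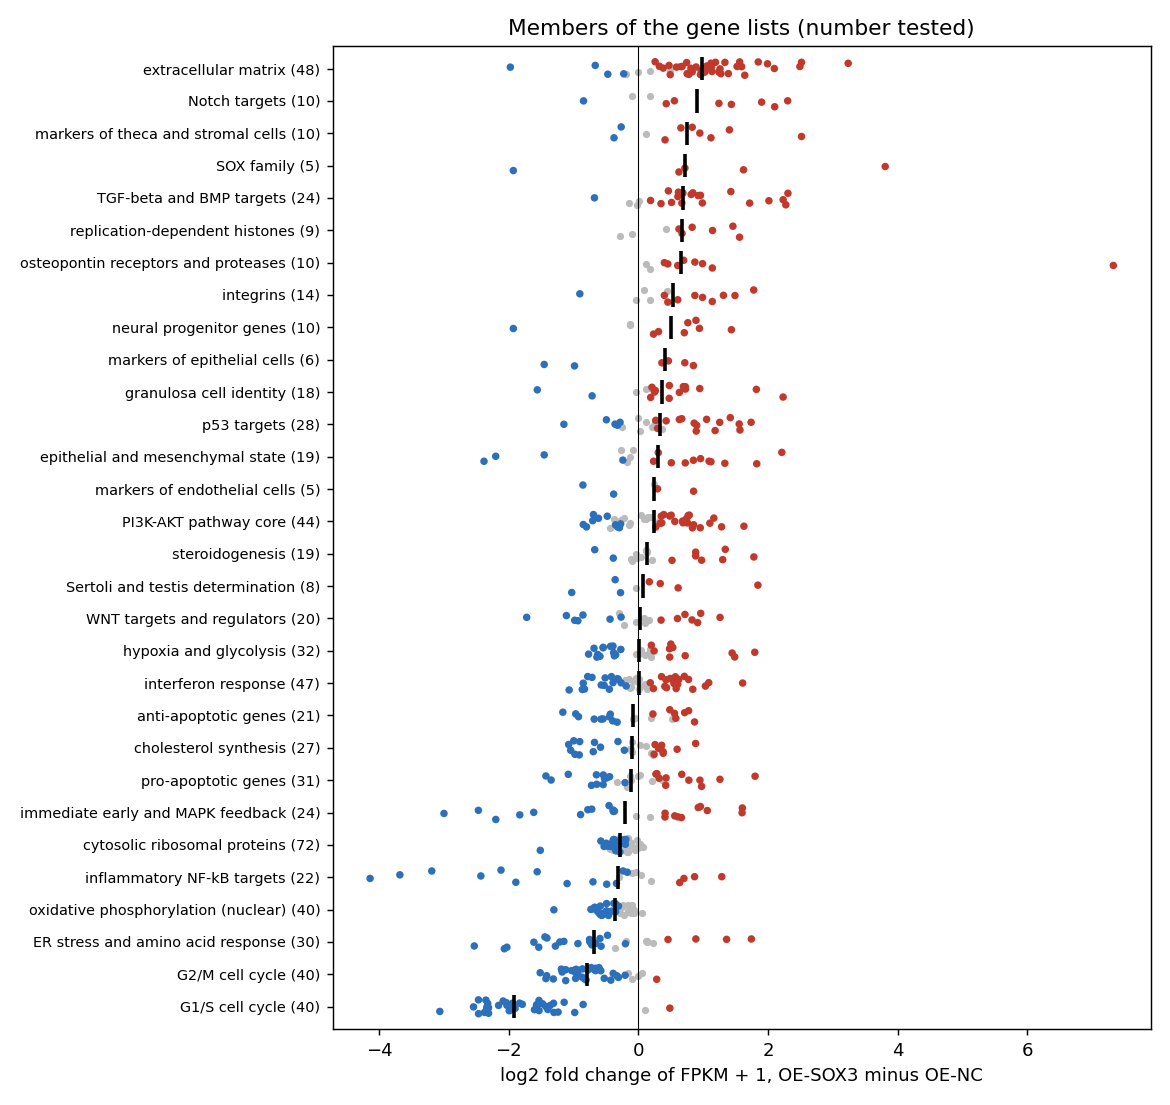
Log2 fold change (horizontal axis, log2 of FPKM + 1, OE-SOX3 minus OE-NC) of each tested member of the 30 lists with at least 5 tested members. Red points rose, blue points fell, grey points did not pass, and a black bar marks the list median, from -1.92 for G1/S genes to 0.98 for extracellular matrix genes.

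Steroidogenic and granulosa cell genes were measured because KGN cells model granulosa cells. STAR, which carries cholesterol into mitochondria, rose from 33.6 ± 0.214 to 118 ± 3.37 FPKM (SD, n = 3 per group), and the cholesterol transporter gene STARD4 rose from 6.6 to 13 FPKM. AKR1C1 (24.5 to 61.9 FPKM) and AKR1C2 (9.63 to 25.9 FPKM), near-identical reductase genes that can share reads, also rose. Of 19 steroidogenesis genes tested, 7 rose, 2 fell and 10 did not pass (9 adjusted over the list alone; median 0.13, camera adjusted p = 0.0454; adjusted p = 0.211 with an estimated correlation). This call was lost with the replicate number as a block (adjusted p = 0.0531) and without OE-NC replicate 3 (adjusted p = 0.0691), in a range of 0.0165 to 0.0691 over alternatives. Of 18 granulosa identity genes, 13 rose, 2 fell and 3 did not pass (15 adjusted over the list alone; median 0.37, camera adjusted p = 0.0138; adjusted p = 0.211 with an estimated correlation). INHBA, the inhibin beta A subunit, rose from 0.488 to 6 FPKM, the gap junction gene GJA1 from 24.9 to 90.3 FPKM and the transcription factor gene GATA4 from 0.349 to 1.09 FPKM, while the cumulus matrix gene PTX3 fell from 285 to 95.9 FPKM.

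Genes of Sertoli cells and testis determination went both ways, 4 higher and 3 lower of 8 tested (7 adjusted over the list alone; median 0.07, camera adjusted p = 0.765). SIX4 rose from 1.1 to 6.51 FPKM and LHX9 from 0.335 to 1.04 FPKM, and CLDN11 fell from 2.11 to 0.516 FPKM. Of 5 tested SOX genes, 4 rose and 1 fell (5 adjusted over the list alone; median 0.72, camera adjusted p = 0.0553). SOX3 itself is among the 4 rises, so the list is not independent of the overexpression. The other 4 genes, 3 higher and 1 lower with a median of 0.67, are too few for a list test. SOX4 rose from 0.417 to 3.37 FPKM, and SOX2, a close relative of SOX3 that is used as a pluripotency and neural progenitor marker, fell from 7.52 ± 0.861 to 1.23 ± 0.0632 FPKM (SD, n = 3 per group). The SOX set passed without OE-SOX3 replicate 1 (adjusted p = 0.0445, range over alternatives 0.0445 to 0.477). Of 10 neural progenitor genes, 7 rose, 1 fell and 2 did not pass (8 adjusted over the list alone; median 0.51, camera adjusted p = 0.0792), with DLL1 (0.435 to 2.88 FPKM) and NCAM1 (8.07 to 13.8 FPKM) higher. That list passed with no filter on low values (adjusted p = 0.0271, range over alternatives 0.0271 to 0.123), where its median was 0.03.

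NF-kB target genes and ER stress genes were lower. Of 22 NF-kB target genes tested, 13 fell, 4 rose and 5 did not pass (17 adjusted over the list alone), with CSF2, CCL20, CXCL1 and CXCL3 (102 to 22.6 FPKM) among those that fell. The list median was -0.32 (camera adjusted p = 0.049; adjusted p = 0.211 with an estimated correlation). This call was lost without OE-NC replicate 3 (adjusted p = 0.0684) and under quantile normalization (0.0776), removal of length and GC trends (0.0669) and limma-voom on recovered reads (0.0505), with a range of 0.00791 to 0.0786 over alternatives. Genes of the ER stress and amino acid response fell, 20 of 30, with 4 higher and 6 not past (24 adjusted over the list alone). The serine synthesis gene PSAT1 (53.1 to 12.3 FPKM), the glutathione-degrading enzyme gene CHAC1 (6.85 to 0.357 FPKM) and TRIB3 (17.6 to 6.65 FPKM) fell, and CREBRF rose (0.725 to 4.77 FPKM). That list had a median of -0.69 (camera adjusted p = 0.0061; adjusted p = 0.211 with an estimated correlation). Immediate early and MAPK feedback genes split into 10 higher, 12 lower and 2 not past of 24 (22 adjusted over the list alone; median -0.21, camera adjusted p = 0.833). Their median was -0.12 without OE-NC replicate 2 and -0.13 without OE-NC replicate 3. JUN (78.0 to 16.2 FPKM) and EGR1 (23.5 to 3.42 FPKM) fell, and the phosphatase gene DUSP4 rose (0.655 to 2.46 FPKM). Interferon response genes also split, 19 higher, 16 lower and 12 not past of 47 (35 adjusted over the list alone; median 0.01, camera adjusted p = 0.833). Among them STAT2 rose from 17.1 to 37.3 FPKM and OAS3 fell from 36.3 to 16.7 FPKM. The interferon median was -0.03 without OE-NC replicate 1 and 0.04 without OE-NC replicate 3.

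Cholesterol, hypoxia, WNT and epithelial and mesenchymal genes held members that rose and members that fell, and camera called none of these lists. Camera tests a list for a shared direction, so it cannot read a shift between epithelial and mesenchymal states, whose genes the last list pools. Of 27 cholesterol synthesis genes, 8 rose, 11 fell and 8 did not pass (19 adjusted over the list alone; median -0.10, camera adjusted p = 0.805), and the median was -0.20, -0.01, -0.02 and -0.05 without OE-NC replicate 1, 2 or 3 or OE-SOX3 replicate 1. It included MVK, which encodes mevalonate kinase and fell (18.2 to 8.73 FPKM). Of 32 hypoxia and glycolysis genes, 10 rose, 13 fell and 9 did not pass (23 adjusted over the list alone). The glucose transporter gene SLC2A3 (7.68 to 23.3 FPKM) and the collagen crosslinking gene LOX (32.3 to 114 FPKM) rose, and VEGFA fell (62.7 to 41.2 FPKM). That list's median was 0.02 (-0.07 without OE-NC replicate 1, 0.05 without replicate 2 or 3) and its camera direction was down (adjusted p = 0.993). Of 20 WNT genes, 7 rose, 7 fell and 6 did not pass (14 adjusted over the list alone; median 0.02, mean -0.04, camera direction up with adjusted p = 0.888), with WNT5A higher (2.74 to 7.95 FPKM) and SFRP1 lower (41.7 to 22.6 FPKM). The WNT median was -0.08 without OE-NC replicate 1 and 0.09 without OE-NC replicate 2. Of 19 genes of epithelial and mesenchymal state, 11 rose, 4 fell and 4 did not pass (15 adjusted over the list alone; median 0.31, camera adjusted p = 0.11). The mesenchymal transcription factor gene TWIST1 rose from 17.4 to 64.0 FPKM, and the desmosome gene DSP, an epithelial gene, rose from 4.78 to 25.8 FPKM. The epithelial genes KRT18 (142 to 26.5 FPKM) and CLDN1 (35.0 to 6.85 FPKM) fell.

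Ribosomal protein and oxidative phosphorylation genes, with median gene lengths of 1114 and 1236 bp, were lower as lists. Of 72 ribosomal protein genes, 29 fell, 0 rose and 43 did not pass, and 1 changed when adjusted over the list alone. RPL29 went from 540 ± 25.9 to 442 ± 1.99 FPKM (SD, n = 3 per group). The list's median log2 fold change was -0.29 (camera adjusted p = 0.00216; adjusted p = 0.789 with an estimated correlation). It was -0.16 without OE-NC replicate 1, the library that stood apart by gene length, and -0.02 with length and GC trends removed, where the call was lost (adjusted p = 0.908, range over alternatives 0.000119 to 0.908) together with that of RPL29. Of 40 nuclear oxidative phosphorylation genes, 23 fell, 0 rose and 17 did not pass (23 adjusted over the list alone; median -0.37, camera adjusted p = 0.00216; adjusted p = 0.689 with an estimated correlation). NDUFA9 fell from 8.65 to 5.16 FPKM and ATP5MC1 from 192 to 76.5 FPKM. With length and GC trends removed this list's median was -0.12 and its call was lost (adjusted p = 0.14, range over alternatives 0.000146 to 0.14). Of the 15 mitochondrially encoded genes, 0 were in the table used here.

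Markers of leukocytes, endothelial cells and epithelial cells went both ways, and theca and stromal markers rose. Of the leukocyte markers 3 could be tested, too few for a list test, and the actin-bundling gene LCP1 rose (17.4 to 38.4 FPKM) while CSF1R (4.68 to 1.42 FPKM) and CD68 (78.1 to 56.0 FPKM) fell. Of 5 endothelial markers, 2 rose, 2 fell and 1 did not pass (5 adjusted over the list alone; median 0.25, camera adjusted p = 0.833), with EGFL7 higher (3.03 to 6.27 FPKM) and ENG lower (50.4 to 27.1 FPKM). The endothelial median was 0.15 without OE-NC replicate 1. Of 6 epithelial markers, 4 rose and 2 fell (6 adjusted over the list alone; median 0.41, mean -0.01, camera adjusted p = 0.666), with CLDN7 higher (0.247 to 1.25 FPKM) and KRT7 (118 to 42.2 FPKM) and PAX8 (8.27 to 3.69 FPKM) lower. Of 10 theca and stromal markers, 7 rose, 2 fell and 1 did not pass (9 adjusted over the list alone; median 0.74, camera adjusted p = 0.0298; adjusted p = 0.211 with an estimated correlation). They included COL1A1, PDGFRA (6.43 to 18.6 FPKM), ACTA2 (60.8 to 133 FPKM) and DCN (23.4 to 37.5 FPKM). Of the 30 lists tested, camera called 16, 10 of them higher and 6 lower in OE-SOX3, and fry called 23, of which 15 were shared. The 8 lists that fry alone called were PI3K-AKT, Sertoli and testis determination, SOX family, neural progenitor, epithelial and mesenchymal state, interferon response, cholesterol synthesis and immediate early genes. The ribosomal protein list was called by camera and not by fry (fry adjusted p = 0.0779). With an estimated correlation camera called 0, with 6 lists at an unadjusted p under 0.05.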

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

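The alternatives with other scalings, trend removal, limma-voom and treat were chosen after seeing the data. The comparison gave 7686 changed genes, and 6557 to 9076 over the 16 other fits, which include leaving out each library (6557 without OE-SOX3 replicate 2, 9076 without OE-NC replicate 1). The rises of SOX3 (3.76 to 7.45, log2) and SPP1 (7.24 to 7.76) passed in each of these fits, and 12 to 18 lists were called against 16. Requiring at least a 2-fold change left 1348 genes (616 higher, 732 lower), and limma's treat against 1.2-fold left 4712 (2221 higher, 2491 lower), because both thresholds are stricter. With an estimated correlation, camera called 0 lists, the smallest adjusted p being 0.211, and fry called 23. With the replicate block 8031 genes and 15 lists were called. Besides the steroidogenesis list, the block changed no call of a named gene or list, and together with removal of length and GC trends it gave 8096 genes and 12 lists. Among named genes and lists over all fits, 2488 values stayed on their side of the threshold, 19 fell short of it and 11 newly passed it, and 0 called values reversed. The median took both signs over the fits in 6 of the 14 lists not called and in 0 of the 16 called lists. The histone list had too few members with GC content for a value with trends removed. Settings chosen before the data were examined that need counts (other size factors, scaling to the library total, a negative binomial Wald test and a count-based test against a minimum fold) were not run. With 3 libraries per group and 18039929 to 20335307 reads, genes under 1 FPKM were not tested (5495 genes below the filter).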

Other observations

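The gene lists in this part were written after the genes with the largest changes had been seen, and the tests of FOXO-associated and YAP-associated genes were chosen after the result was seen. Adjusted p-values are from camera over 12 sets, the 6 lists with and without those genes. With an estimated correlation, which also lowers its degrees of freedom, camera called none of these sets (smallest adjusted p = 0.0545, with 8 of the 12 at an unadjusted p under 0.05). Each rise or fall of a list below therefore rests on camera with the preset correlation. Circadian clock genes rose, 10 of 14, with 2 lower and 2 not past the threshold (median log2 fold change 1.13, adjusted p = 0.00051). Without the gene seen first the median was 0.94 (adjusted p = 0.00145; adjusted p = 0.0545 with an estimated correlation). NR1D2 (2.37 to 14.1 FPKM), PER1 (7.35 to 29.1 FPKM), TEF (0.4 to 4.69 FPKM) and CRY2 (0.786 to 3.81 FPKM) rose with NR1D1, CRY1 fell slightly (5.9 to 4.98 FPKM), and CLOCK stood at 5.4 and 4.73 FPKM without passing. Glucocorticoid-responsive genes rose, 14 of 16 with 2 lower (median 1.37, adjusted p = 5.53e-06), and without those seen first 11 of 13 rose (median 1.04, adjusted p = 0.000274; adjusted p = 0.0545 with an estimated correlation). They included TSC22D3 (84.3 to 501 FPKM), GLUL (35.4 to 292 FPKM) and ZBTB16 (7.73 to 23.0 FPKM). Of that list 4 genes were also in lists fixed earlier. The time of harvest is not given in the sources used here, so for these lists it cannot be told apart from the group.

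Genes of ribosome biogenesis and MYC-associated genes fell, 23 of 26, with 0 higher and 3 not past (median -0.94, adjusted p = 7.77e-07). Without the gene seen first 22 of 25 fell (median -0.92, adjusted p = 1.11e-06; adjusted p = 0.0545 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, fell from 48.4 to 7.13 FPKM, NOP56 from 85.9 to 22.6 FPKM and NCL, which encodes nucleolin, from 209 to 85.1 FPKM, whereas MYC itself stood at 25.1 and 24.0 FPKM without passing. Lysosomal genes had 12 higher, 5 lower and 8 not past of 25 (median 0.27, adjusted p = 0.158). The splicing kinase gene CLK1, chosen after its value was seen, rose from 11.2 to 77.4 FPKM.

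G1/S genes were lower in OE-SOX3 by a median of 1.92 on the log2 scale (-1.92), in a comparison whose labels name SOX3 overexpression. A gene length and GC trend as the whole cause is argued against by a median of -1.75 with those trends removed, and OE-NC replicate 1 alone by a median of -1.84 without that library. One hypothesis is that PI3K-AKT output was lower in the OE-SOX3 cells, which may release FOXO factors. Of 23 FOXO-associated genes other than those seen first, 19 rose and 1 fell (median 1.1, camera adjusted p = 1.11e-06). The set did not pass the threshold with an estimated correlation (camera adjusted p = 0.0545). Rises included MXI1 (1.8 to 9.9 FPKM), GABARAPL1 (7.22 to 35.1 FPKM) and CDKN1B (10.2 to 18.8 FPKM). This list was written after the result was seen, and 12 of its genes were also in lists fixed earlier. It is therefore not independent support for the hypothesis, and transcript levels do not measure kinase activity. A difference in culture density cannot be told apart from the group, because density is not given and may differ with it. YAP-associated genes, taken as a reading of density, do not decide this. They went both ways (8 higher and 6 lower of 21, median 0.22, camera adjusted p = 0.193), with CCN2 higher (149 to 602 FPKM) and ANKRD1 lower. An effect of SOX3 on proliferation stays open, and neither cell number nor density at harvest is given in the sources used here.

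Ribosomal protein genes were lower in OE-SOX3 by a mean of 0.28 on the log2 scale (-0.28, SD between libraries 0.15). A length and GC trend may account for this difference: with those trends removed it was -0.03 (SD 0.05), and the call ended because the difference itself shrank. The list's median gene length was 1114 bp, and removing a trend also removes any biological change that follows length. An effect of SOX3 on these genes stays open and was not tested apart from the trend.

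OE-NC replicate 1 differed from the other OE-NC libraries 3.03 times as much, as an SD over genes, as those differed from each other. A gene length and GC trend in that library as the whole cause is argued against by a ratio of 2.67 after the trends were removed. With the trends removed, the deviations of OE-NC 1 correlated at 0.464 with those of OE-SOX3 1. They correlated at -0.274 and -0.277 with those of OE-SOX3 2 and 3. These negative values are not separate evidence, because deviations within a group sum to 0. Part of the difference may therefore be shared by the libraries numbered 1, which was not tested further. The remaining difference stays open, and no biological explanation was tested, because the labels give nothing but the replicate number that sets this library apart.

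The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 7686 changed genes and was 1 of 10 with a count as large, and the highest other gave 0, both among the 3 others that part all replicate pairs and among the rest.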
